A study of Mus musculus with 3 samples.

How the data were processed

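RNA was measured in 3 libraries of RAW264.7, a mouse macrophage cell line derived from a tumour induced by Abelson murine leukaemia virus. The groups were cells seeded at low density, cells seeded at high density, and high density cells given bacterial lipopolysaccharide (LPS). LPS was given at 500 ng/ml for 24 h, starting 24 h after seeding. No time from seeding to harvest was recorded here for the untreated libraries. Time in culture may therefore differ between LPS-treated and untreated cells. Each group had 1 library, so no difference has a replicate check, no p-value was computed here, and all values describe these libraries rather than the conditions. Total RNA was taken with RNAiso Plus and made into libraries by a standard Illumina procedure, per the labels' protocols.

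The submitters' processing notes name FastQC, fastp, TopHat2 and Cuffdiff and the builds GRCm38 and mm10, without versions. The gene annotation and the scaling method are not given in the sources used here. The authors deposited 2 tables, one for each pair of libraries, and their column names are those of a Cuffdiff gene test table. Expression is therefore taken as FPKM (fragments per kilobase of transcript, relative to the fragments of the library) as deposited, with Cuffdiff's own scaling within each table. The authors' log2 ratio, test statistic (a score with no fixed range), p-value and q-value of each locus are in the same tables, per the file headers. The smallest deposited p-value was 5e-05 in both tables. Only those values described as from the authors' deposited table come from that test, which was made without replicates. Loci are given on RefSeq sequences of GRCm38, and their starts were raised by 1 to be 1-based. The tables held 49850 and 49971 rows. No per-sample column was left unused.

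The high density library is in both tables and was scaled separately in each. Over the 10394 genes at 1 FPKM or more in both, its value in the LPS table was lower by a median of 0.13 on the log2 scale (2.5% to 97.5% of genes, -0.29 to 0.07), and 38 genes differed by 2-fold or more. Ratios were therefore made only within a table.

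Reads were not counted here. In single-transcript genes of 1000 bases or more, the lowest values times the transcript length gathered at a step, read as 1 fragment. The step lay at 0.0606 FPKM times kilobases at low density and 0.0602 at high density. In the LPS table it lay at 0.0545 for high density and 0.0686 for LPS. On Cuffdiff's scale, 1 FPKM over 1 kilobase thus corresponds to about 16.5, 16.6, 18.3 and 14.6 fragments in that order, so that values near 1 FPKM have wide counting error.

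Rows with no gene symbol were set aside, 1154 and 1233 of them. For a symbol with several rows, the row with the highest mean was used. Genes counted as measured had 1 FPKM or more in either library and no failed status, which left 10911 genes for density and 11010 for LPS. Ratios are log2((FPKM + 1)/(FPKM + 1)), a scale that understates the change of low genes, and a gene was counted as 2-fold higher or lower at a log2 ratio of 1 or more, or -1 or less. An exact 0 can be a failed estimate in such tables, so a gene at 0 is said to be listed at 0.

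A set of 37 gene lists, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn with replacement and matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5 with at least 5 members measured. Strand is not given in the sources used here, so overlapping genes such as Ddit3, Ankrd37, Pltp, Ppp1r15a, Ikbke, Traf1 and Mcm7 cannot be separated from their neighbours. Members joined with a neighbour into 1 row were left out of the lists. The rule named, per comparison, the 10 largest and 10 smallest ratios among genes of 10 FPKM or more in the higher library, without predicted models, Rik clones, small RNAs and pseudogenes. It also named up to 4 members of each list that stood apart, up to 2 members past 2-fold of each other list, 10 genes chosen beforehand (Tnf, Il6, Il1b, Nos2, Ptgs2, Arg1, Cdkn1a, Mki67, Tlr4 and Cd14), and 5 genes per pair of directions in both comparisons. The exclusions did not cover LOC gene models or mitochondrial tRNAs, which took many of the largest and smallest places while listed at 0 in 1 library. A second selection was therefore made after the values were seen, of the 10 largest and 10 smallest ratios among protein-coding genes of 10 FPKM or more in the higher library and above 0 in both. Lists of glycogen metabolism and iron handling were also drawn up after the values were seen. Some genes that the rule names are not reported here. Genes outside the fixed rule are described as chosen after their values were seen.

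The steps were tested on simulated data built on the real values, with 100 genes raised and 100 lowered 4-fold. The changed genes were drawn only from those with a mean of 2 FPKM or more, so recovery of lower genes was not tested. Normal noise was added to 1 library, with the same spread at every expression level. Its standard deviation, from the spread of the real ratios, was 0.41 on the log2 scale for density and 0.61 for LPS. The simulation therefore checks the steps and gives no rate of false calls in these libraries. In the density comparison, 97% of raised and 96% of lowered genes were recovered among 10785 genes, and 0.84% of unchanged genes passed 2-fold. In the LPS comparison the values were 97%, 93% and 6.79% among 10826 genes. Of 200 random lists without a change, 3.5% and 6.5% stood apart.

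Alternatives were a pseudocount of 0.1 or 5, no filter or 5 FPKM, centring, upper-quartile scaling, rescaling both libraries to the same sum without the 20 highest genes, the high density value from the other table, status OK only, FPKM summed per symbol, fewer gene types, a log2 threshold of 1.5, unmatched random lists and stricter q limits. Rescaling without the 20 highest genes came before the minimum and the pseudocount were applied. It raised all values and so weakened both. After the data were examined, removal of the trend on transcript length and GC was added, as was leaving out transcripts under 300 bases, symbols with several rows and genes listed at 0, and keeping only protein-coding genes. Lengths and GC came from the longest GENCODE transcript of each symbol and covered 92.0% and 91.8% of measured genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.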

Results

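Gene expression was measured by RNA sequencing in RAW264.7, a mouse macrophage cell line, at low density, at high density, and at high density with bacterial lipopolysaccharide (LPS), which macrophages sense through Toll-like receptor signalling. Each group had 1 library. Levels are FPKM as Cuffdiff gave them, and 1 FPKM over 1 kilobase of transcript corresponded to about 16.5 fragments in the low density library, 16.6 in the high density library (18.3 in the table with LPS) and 14.6 in the LPS library. Per the study's design text, high density was set against low density, and LPS-treated high density cells against untreated ones. Because no group has a second library, no difference could be set against a replicate spread. Positions are on GRCm38.

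The first comparison asked how expression differed at high cell density. Targets of hypoxia-inducible factor (HIF) other than glycolytic enzymes were higher at high density: 17 of 21 measured members were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.67 (percentile 100). Glycolytic genes were also higher, 8 of 23 by 2-fold or more (median 0.80, percentile 100). DNA replication genes were lower as a group, with a median of -0.47 (percentile 0), 2 of 39 being at least 2-fold lower and 37 within 2-fold. Tfrc, the transferrin receptor (chromosome 16, 32608896 to 32632794), was 84.5 FPKM at low density and 11.7 at high density.

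Among HIF targets, Selenbp1 (methanethiol oxidase, chromosome 3, 94933083 to 94944758) was 9.22 FPKM at low density and 226 at high density. Adm, encoding the peptide adrenomedullin (chromosome 7, 110625467 to 110630906), was 0.822 and 38.2 FPKM. Ankrd37 (chromosome 8, 45975506 to 46000414), an ankyrin repeat gene overlapping Ufsp2, was 6.10 and 148 FPKM. Ndrg1 (chromosome 15, 66929318 to 66969641) was 23.5 and 227 FPKM. Of the 21 members, 9 were called higher in the authors' deposited table, Selenbp1 and Ndrg1 among them with q = 0.0217. In glycolysis, the phosphofructokinase genes Pfkp and Pfkm had log2 ratios of 1.58 and 1.18, the glucose transporter gene Slc2a1 1.42 and the aldolase gene Aldoc 1.29.

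The list of p53 targets and cell-cycle inhibitors was higher, with a median of 0.55 (percentile 100) and 3 of 23 members past 2-fold. Ccng2, an atypical cyclin, was 9.51 FPKM at low and 74.6 at high density, Bbc3, a pro-apoptotic BH3-only gene, had a log2 ratio of 1.17 and the CDK inhibitor gene Cdkn2d 1.03, while Cdkn1a, encoding p21, was 0.96. Cytosolic ribosomal protein genes were higher as a group (median 0.54, percentile 100), with 0 of 76 past 2-fold. Rpl13, Rpl41, Rpl22l1 and Rpl13a had log2 ratios from 0.76 to 0.80. The ribosomal RNA loci Rn45s and Rn18s-rs5 were 1937 and 7947 FPKM, and 2333 and 6450 FPKM. Ribosomal RNA loci made up 0.64% of the summed FPKM at low density and 1.88% at high density. Whether this difference lay in the cells or in the preparation of the 2 libraries was not tested.

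Targets of the stress factor ATF4 were higher (median 0.26, percentile 99.41), with 6 of 33 past 2-fold. The largest was Ddit3 (CHOP) at 1.79, which overlaps Mars and other genes. The pseudokinase gene Trib3 was at 1.46, Nupr1 at 1.33 and Atf3 at 1.13. Lysosome and autophagy genes had a median of 0.27 (percentile 99.26), 2 of 38 past 2-fold, with Map1lc3a (LC3A) at 1.16, Wipi1 at 1.04, the kinase gene Ulk1 at 0.82 and the cathepsin gene Ctsa at 0.81. LXR targets had a median of 0.36 (percentile 98.22), 1 of 11 past 2-fold, with Pltp at 1.05, which overlaps Ctsa, the cholesterol transporter gene Abca1 at 0.76, Npc2 at 0.66 and Nr1h2 at 0.51. Antigen presentation genes had a median of 0.31 (percentile 98.41), 2 of 14 past 2-fold, with Cd74, the invariant chain, at 157 FPKM and 368, Cd83 at 1.21, Psmb9 at 0.87 and Cd40 at 0.82. Of the 26 genes listed, 14 were measured. Psmb9 had 4 rows and was near the floor, at 1.23 and 3.08 FPKM. Genes with 4 rows were often listed at 0, as given below for Tnf. The LXR and antigen presentation lists no longer stood apart under 5 alternatives each, at percentiles from 92.42 to 97.31 and from 85.58 to 97.44. Removing the trend on transcript length and GC took the ATF4 list to percentile 95.44. After rescaling without the 20 highest genes, which moved the median of all genes to -0.21, list medians were 0.035 for ATF4 targets, 0.041 for lysosome and autophagy, 0.072 for antigen presentation, 0.18 for LXR targets, 0.30 for ribosomal proteins and 0.35 for the p53 list.

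In the DNA replication list, the ribonucleotide reductase gene Rrm2 had a log2 ratio of -1.15, the cyclin gene Ccne2 -1.10, the origin licensing gene Cdc6 -0.94 and the helicase gene Mcm4 -0.92. Endoplasmic reticulum chaperones had a median of -0.28 (percentile 0), with Hyou1 at -0.83, Creld2 at -0.81, Pdia4 at -0.78 and Selenos at -0.72, and 1 of 26 higher, the disulfide isomerase gene P4hb at 1.27, named after its value was seen. Interferon-stimulated genes had a median of -0.31 (percentile 0.1), with Oasl1 at -0.86, Oas2 at -0.84, Rtp4 at -0.79 and Irgm1 at -0.55. Of 24 measured members, 1 was higher, the exonuclease gene Isg20 at 1.10. The list held 51 genes. The members named were low: Oasl1 was 2.79 and 1.09 FPKM, Oas2 6.20 and 3.01, and Rtp4 1.62 and 0.51. Irgm1, with 4 rows, was 1.82 and 0.92 FPKM, and Isg20 1.26 and 3.86. Cholesterol synthesis genes had a median of -0.22 (percentile 0.35), 1 of 24 past 2-fold, with Hsd17b7 at -1.07, Idi1 at -0.79, Lss at -0.61 and Sc5d at -0.61. Toll-like receptors and adaptors had a median of -0.18 (percentile 1.46), 0 of 29 past 2-fold, with Tlr7 at -0.79, Tlr9 at -0.78, Tlr2 at -0.69 and the co-receptor gene Cd14 at -0.61, while Tlr4 was 15.1 and 11.7 FPKM. Cytosolic heat shock proteins had a median of -0.18 (percentile 1.11), 0 of 16 past 2-fold, with Chordc1 and Dnaja1 at -0.59, Hsph1 at -0.58 and Hsp90aa1 at -0.50, and stood within the range of unmatched random lists (percentile 4.8). The same rescaling gave medians of -0.71 for DNA replication, -0.60 for interferon-stimulated genes, -0.52 for endoplasmic reticulum chaperones, -0.46 for cholesterol synthesis, -0.46 for Toll-like receptors and -0.42 for heat shock proteins. With no filter, the interferon-stimulated and heat shock medians were -0.16 and -0.12.

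Single inflammatory genes went in different directions. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226), was 0.974 FPKM at low density and 15.9 at high density, and is called higher in the authors' deposited table (q = 0.0217). Ccl2, a monocyte chemokine, was 10.2 and 0.80 FPKM, and Gpr84, a fatty acid receptor (chromosome 15, 103308233 to 103310670), was 56.3 and 12.2. Il1rn, the interleukin 1 receptor antagonist, was 38.0 and 12.8 FPKM, and Acod1, which makes itaconate, 27.2 and 9.29. Il1b and Ptgs2 were under 1 FPKM in both libraries, Il6 was listed at 0, and Arg1 was at or near 0. Mki67, a proliferation marker, was 58.3 and 48.3 FPKM.

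Among lists that did not stand apart, the medians were -0.15 for inflammatory cytokines, -0.09 for NF-kB pathway members, -0.13 for macrophage identity, -0.11 for inflammasome and cell death and -0.04 for alternatively activated macrophage genes. They were -0.07 for integrins and adhesion, -0.07 for YAP and TAZ targets, 0.04 for mitosis, 0.05 for immediate early genes, 0.10 for extracellular proteases, 0.17 for osteoclast genes and 0.02 for reference genes. For oxidative phosphorylation, the citrate cycle, NRF2 targets and fatty acid synthesis they were 0.17, 0.12, 0.10 and 0.00030. Some came to stand apart under alternatives. Inflammatory cytokines did at 5 FPKM (-0.34) and without the trend on length and GC (-0.23), and macrophage identity with no filter (-0.15) and in other settings given below. Integrins did without the trend (-0.16), and oxidative phosphorylation did against unmatched random lists. Of the lists that did not stand apart, the medians of mitosis, immediate early, protease, osteoclast, reference, oxidative phosphorylation, citrate cycle, NRF2 and fatty acid genes were negative after rescaling without the 20 highest genes, so no direction is given for them. None is given either for YAP and TAZ targets, at 0.0098 without the trend on length and GC, or for alternatively activated genes, at 0.052 with no filter on low values. Of 12 inflammatory cytokine genes, 1 was at least 2-fold higher, Nos2, and 3 lower, Ccl2, Ccl4 and Cxcl2, the last at -1.02. Of 28 NF-kB members 0 were higher and 2 lower, Il1rn and Acod1. Of 20 immediate early genes, 3 were higher and 3 lower, with Ier3 at 1.68, Fos at -1.64 and Atf3. Maff at 1.26, Dusp6 at -1.38, Fosl1 at -1.05, Cxcl2 and the urokinase receptor gene Plaur at -1.04 were named after their values were seen. Other members past 2-fold included the protease inhibitor gene Serpinb9 at -1.08, Mcl1 at 1.26, Casp6 at 1.08, the scavenger receptor genes Msr1 at 49.1 and 20.3 FPKM and Cd36 at 17.5 and 8.26, Lpin1 at 1.12 and Pgk1 at 1.06. Markers of fibroblasts and epithelial cells had 0 members at 1 FPKM, and those of lymphocytes, neutrophils and dendritic cells had 2, 3 and 1, with medians of 0.22, 0.09 and 0.54. The histone list matched only 9 symbols as written, of which 2 were measured, with Hist1h4n at 1.17. The mitochondrial list matched 0 symbols as written. Taken by chromosome after the data were examined, 10 mitochondrial mRNA loci had a median of -0.72, 0 past 2-fold, for example ND1 at 6474 and 3579 FPKM.

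**Figure D1:**
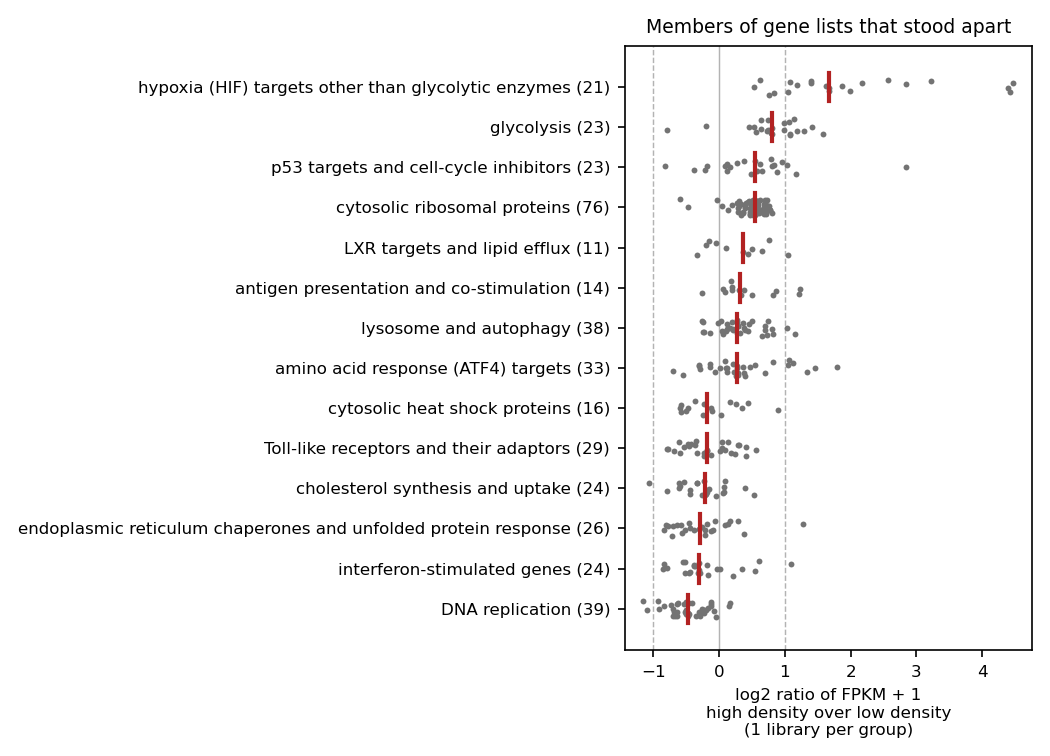
Log2 ratio of FPKM + 1, high density over low density, for each measured member (grey points) of the 14 gene lists that stood apart, with the number measured in parentheses and the list median as a red bar. HIF targets have the highest median, 1.67, and DNA replication the lowest, -0.47.

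In all, 386 of 10911 genes were at least 2-fold higher and 99 lower at high density. Of these, 32 and 24 were listed at 0 in 1 library, and for them no fold is given. The 10 largest ratios held 7 such loci, among them the mitochondrial tRNAs TrnN and TrnT, listed at 0 at low density. The 10 smallest also held 7, among them Rny1, a Y RNA listed at 0 at high density. Chosen after their values were seen, protein-coding genes with large ratios were Selenbp2 at 3.79, Tnfrsf9 (the receptor 4-1BB) at 3.95, Ephx1 (an epoxide hydrolase) at 3.15 and Cmss1 at 4.30. Cmss1, at 87.2 and 1737 FPKM, had 2 rows and overlaps Filip1l and other genes, so its value may not be its own. In the authors' deposited table it has q = 0.999. At the other end were Il1rl1 (the interleukin 33 receptor) at -1.55, Id3 at -1.38, Ctsc at -1.31 and Ccl4 at -1.30, which shares its locus with Ccl3. The authors' deposited table calls 31 loci higher and 2 lower, Tfrc and Gpr84. The share of 2-fold genes that were higher was 79.6%. It was 48.6% after rescaling both libraries to the same sum without the 20 highest genes, where the median gene was at -0.21 against 0.01. The rescaling also raised all values against the pseudocount and the minimum, with 11885 genes measured, so the share does not reflect scaling alone.

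The second comparison asked what LPS changed in high density cells. Interferon-stimulated genes had a median log2 ratio of 2.91 (percentile 100), 34 of 35 at least 2-fold higher and 1 lower, the transcription factor gene Irf1 at -1.22, named after its value was seen. Inflammatory cytokines, chemokines and effectors had a median of 2.5 (percentile 100), with 22 of 23 higher. These 2 lists held 51 and 32 genes, of which 35 and 23 were measured. A member listed at 0 without LPS was measured only at 1 FPKM or more with LPS, which alone gives a log2 ratio of 1 or more. The counts of higher members are therefore partly fixed by the filter. To a lesser degree the filter also favours higher members in other lists below. There, Ptpn14, Mmp9, Myc, Gadd45a and Fosl1, under 1 FPKM without LPS, were measured only through the LPS library. NF-kB pathway members and inhibitors had 1.57 (percentile 100), with 22 of 30 higher. Mitosis genes were lower, with 20 of 34 past 2-fold and a median of -1.10 (percentile 0). The size of the first 2 medians depended on the treatment of low values: over the alternatives run they ranged from 1.61 to 3.65 for interferon-stimulated genes, lowest at a pseudocount of 5, and from 1.78 to 5.09 for cytokines, highest at a minimum of 5 FPKM.

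Lcn2, encoding the iron-siderophore binding protein lipocalin 2 (chromosome 2, 32384637 to 32387739), was 0.326 FPKM without LPS and 618 with it. The chemokine genes Ccl5 (chromosome 11, 83511289 to 83546540) and Ccl2 (chromosome 11, 82035577 to 82037452) were 2.39 and 719, and 0.64 and 293 FPKM. Csf3, the granulocyte colony-stimulating factor (chromosome 11, 98695980 to 98703631), was 0.0551 and 184 FPKM, and Ccl7 was listed at 0 without LPS and at 73.9 with it. Cxcl2 and Cxcl3, joined in 1 row of this table, were 1.01 and 1155 FPKM. In the authors' deposited table, Ccl7 is called higher (q = 0.0174), while Lcn2, Ccl5, Ccl2 and Csf3 have q = 0.999. Il6 was listed at 0 without LPS and at 4.67 FPKM with it, Il1b was 0.0449 and 4.02, Ptgs2 (cyclooxygenase 2) 0.191 and 41.0, and Nos2 14.4 and 111. Tnf had 4 rows, 1 on chromosome 17 and the others on alternate scaffolds, and was listed at 0 in every library, as were Rps18 and Csnk2b of its region, so that no level of Tnf is given. Arg1 was at or near 0 in both libraries.

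In the interferon-stimulated list, the antiviral genes Oasl1, Isg15, Irf7 and Zbp1 had log2 ratios of 6.57, 6.21, 5.99 and 5.82, with Isg15 (chromosome 4, 156165164 to 156200818) at 2.13 and 230 FPKM. In the NF-kB list, Acod1 was 8.49 and 547 FPKM, Il1rn 11.7 and 322, Traf1 (a signalling adaptor) 2.88 and 45.6, and Cd274 (PD-L1) 7.18 and 74.1. Toll-like receptors and adaptors had a median of 0.35 (percentile 98.28), 4 of 29 higher and 1 lower, with Irak2 at 2.30, Ikbke at 1.92, Cd14 at 433 and 1316 FPKM and Ticam1 at 1.27, and with Irf3, named after its value was seen, at -1.04, while Tlr4 was 10.6 and 7.94 FPKM. Under 3 alternatives this list was at percentiles from 94.92 to 96.78. Antigen presentation and co-stimulation had a median of 0.71 (percentile 99.94), 4 of 13 higher, with Cd40 at 2.92, H2-T23 at 2.81, Cd80 at 1.33 and Cd86 at 1.21. Of the 26 genes listed, 13 were measured, and H2-T23 had 3 rows and overlaps H2-T22 and H2-T24.

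Targets of ATF4 had a median of 1.05 (percentile 100), 18 of 34 at least 2-fold higher. The cystathionine lyase gene Cth was 0.631 and 38.1 FPKM, and Atf3, Ppp1r15a (GADD34) and Ddit3 had log2 ratios of 2.57, 2.46 and 2.22. Endoplasmic reticulum chaperones had a median of 0.59 (percentile 99.99), 8 of 26 higher, with Dnajb9 at 2.21, Hspa5 (BiP) at 503 and 2308 FPKM, Sel1l at 1.72 and Selenos at 1.33. Immediate early genes had 0.82 (percentile 100), 9 of 20 higher and 2 lower, with Dusp4 at 3.37, Atf3 at 2.57, Maff at 1.69 and Fosl1 at 1.65. The list of p53 targets and cell-cycle inhibitors had 0.51 (percentile 99.93), 8 of 24 higher and 3 lower, with Plk2 at 3.85, Plk3 at 2.12 and 16.6 FPKM, Mdm2 at 1.89 and Gadd45a at 1.83, and Cdkn1a was 57.0 and 124 FPKM. The lower members, named after their values were seen, were Ier2 at -1.29 and Zfp36l1 at -1.15 among immediate early genes, and Cdkn2c at -1.47, Sesn1 at -1.31 and Ccng2 at -1.10 in the p53 list.

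Extracellular proteases and inhibitors had a median of 0.97 (percentile 100), 7 of 15 higher and 2 lower, with the gelatinase gene Mmp9 at 0.73 and 25.1 FPKM, Slpi at 2.89, Adam8 at 2.09 and Serpinb9 at 1.57. Integrins and adhesion genes had 0.46 (percentile 99.88), 8 of 27 higher and 2 lower, with Itgam at 1.70, the hyaluronan receptor gene Cd44 at 1.57, Itga5 at 1.52 and Itgb7 at 1.24. Alternatively activated macrophage genes had 1.10 (percentile 99.98), 5 of 9 higher and 1 lower. Of the 23 genes listed, 9 were measured, and Arg1 was not among them. Cd36 and Msr1, scavenger receptors, were at 3.03 and 2.91, Myc at 1.83 and Stab1 at 1.15. The other higher member, Tgm2 at 1.10, and the lower members of these lists were named after their values were seen: Plau at -1.05 and Cst3 at -1.30, Itga4 at -1.79 and Icam2 at -1.73, and Clec7a at -1.57. YAP and TAZ targets had 0.81 (percentile 99.8), 3 of 8 higher, with Ptpn14 at 2.34, Dock5 at 3.58 and 11.1 FPKM, Gadd45b at 1.35 and Myof at 0.82. Of the 23 genes listed, 8 were measured, and Ptpn14 was 0.86 FPKM without LPS and 8.41 with it. Osteoclast genes had 0.53 (percentile 98.61), 2 of 11 higher, with Mmp9 at 3.92, the kinase gene Src at 2.37, Tcirg1 at 0.97 and Tnfrsf11a at 0.66. Lysosome and autophagy genes had 0.21 (percentile 97.86), 1 of 39 past 2-fold, with the autophagy receptor gene Sqstm1 at 146 and 1335 FPKM, Ctsb at 0.86 and Ctsl at 0.77. With no filter on low values, the alternatively activated, YAP and TAZ, osteoclast and lysosome lists were at percentiles 96.2, 71.87, 57.95 and 97.47. Their medians were then 0.16, 0.025, 0.022 and 0.21. The lysosome median was 0.095 with upper-quartile scaling and 0.31 without the trend on length and GC, and at a pseudocount of 5 those of proteases and alternatively activated genes were 0.54 and 0.69.

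Among mitosis genes, Ccnb2 (cyclin B2), Plk1 (polo-like kinase 1), Pttg1 (securin) and Kif2c had log2 ratios of -1.82, -1.68, -1.66 and -1.49, and Mki67 was 50.1 and 23.1 FPKM. DNA replication genes had a median of -0.31 (percentile 0.05), 2 of 39 lower by 2-fold, with Tk1 at -1.11, Mcm7 at -1.03, Rfc5 at -0.80 and Rpa2 at -0.80. Fatty acid synthesis genes had -0.49 (percentile 0.01), 2 of 18 lower and 2 higher, with Fasn at -1.71, Scd2 at -1.58, Scd1 at -0.83 and Acaca at -0.78, and with no filter they were at percentile 2.92. Cholesterol synthesis genes had -0.46 (percentile 0.01), 3 of 24 lower, with Acat2 at -1.45, Idi1 at -1.11, Hmgcs1 at -1.04 and Mvd at -0.94. LXR targets had -0.38 (percentile 1.96), 3 of 12 lower and 1 higher, with the lipoprotein lipase gene Lpl at -1.33, Pltp at -1.30, Abcg1 at -1.11 and Mylip at -0.83, and 5 alternatives placed them between percentiles 2.71 and 5.29. HIF targets had -0.41 (percentile 0.07), with 6 lower and 2 higher by 2-fold among 22, and Ankrd37 at -3.88, Selenbp1 at -2.26, Egln1 at -1.93 and Ddit4 at -1.78. A second list of HIF targets, written before its values were seen, had a median of 0.14 (percentile 75.19), with 4 higher and 1 lower by 2-fold among 21, and so did not stand apart with LPS. Higher members, named after their values were seen, included Plin2 at 1.80 and Acsl4 at 1.23 (fatty acids), Npc1 at 1.55 (LXR) and Pgf at 1.71 (HIF). Oxidative phosphorylation subunits had -0.36 (percentile 0.01), 0 of 47 past 2-fold, with Uqcrh at -0.99, Ndufb3 at -0.72, Cox6b1 at -0.71 and Ndufs7 at -0.70. Without the trend on length and GC, the HIF and oxidative phosphorylation medians were -0.21 and -0.21. Beside them, the 10 mitochondrial mRNA loci had a median of -1.27, 6 lower by 2-fold, with ND1 at 3275 and 818 FPKM.

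Among lists that did not stand apart, the medians were -0.17 for glycolysis, -0.16 for NRF2 targets and glutathione, -0.09 for the citrate cycle, -0.08 for cytosolic ribosomal proteins, -0.02 for macrophage identity, 0.03 for cytosolic heat shock proteins, 0.10 for reference genes and 0.26 for inflammasome and cell death. The heat shock and reference medians were negative with upper-quartile scaling, so no direction is given for them. None is given either for macrophage identity, which was positive under 4 alternatives, from 0.035 to 0.094, or for ribosomal proteins, at 0.072 without the trend on length and GC. Of 28 NRF2 and glutathione genes, 4 were at least 2-fold higher and 3 lower, with Fth1 (ferritin heavy chain) at 7152 and 28641 FPKM and Hmox1 (haem oxygenase 1) at 193 and 776. The others, chosen after their values were seen, were Esd at 1.80, Slc7a11 at 1.34, Cbr3 at -1.23, Gclc at -1.09 and Gstm1 at -1.05. Of 23 glycolytic genes, 3 were higher and 2 lower, with Pfkfb3 at 1.68 and Pfkm at -1.35, and, chosen after their values were seen, Slc2a1 at 1.25, Hk3 at 1.01 and Pdk1 at -1.15. In the citrate cycle 1 of 21 was lower, Idh1 at -1.01, and in inflammasome and cell death 6 of 25 were higher and 0 lower, with Casp4 at 2.46 and Mlkl at 1.99. Of 21 macrophage identity genes, 5 were at least 2-fold higher and 3 lower, with Fcgr3 and Cx3cr1 at -2.93 and -2.36 and Itgam at 1.70. The others, named after their values were seen, were Adgre1 (F4/80) at 1.99, Axl at 1.61, Fcgr2b at 1.13, Cebpb at 1.11 and Cebpa at -1.45. The transferrin receptor gene Tfrc was 10.8 and 88.2 FPKM. Markers of fibroblasts and epithelial cells had 0 members at 1 FPKM, and those of lymphocytes, neutrophils and dendritic cells had 3, 3 and 2, with medians of -0.25, 0.03 and 0.31. In these, S100a8 was at 2.10, Elane at -1.13 and Ccl22 at 1.33. The histone list matched 9 symbols and had 3 measured members, with Hist1h2ao at -1.78 and Hist1h4n at 1.31.

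**Figure D2:**
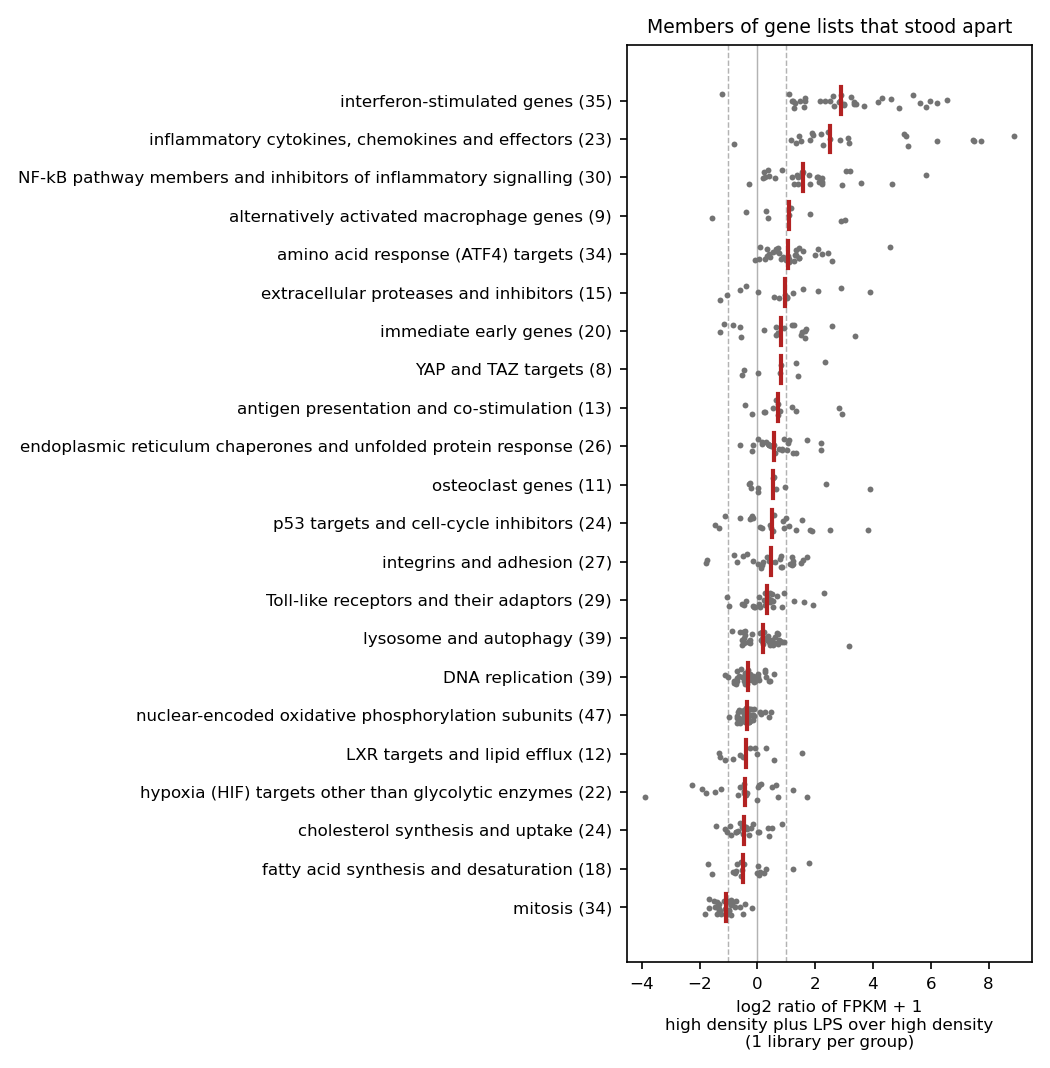
Log2 ratio of FPKM + 1, high density plus LPS over high density, for each measured member (grey points) of the 22 gene lists that stood apart, with the number measured in parentheses and the list median as a red bar. Interferon-stimulated genes have the highest median, 2.91, and mitosis genes the lowest, -1.10.

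With LPS, 947 of 11010 genes were at least 2-fold higher and 643 lower, of which 59 and 38 were listed at 0 in 1 library. Of the 10 smallest ratios, 5 were such loci, TrnN and TrnT among them. The others were Cytip (an adhesion regulator, chromosome 2, 58129139 to 58195549, 20.96 and 0.470 FPKM), Ankrd37, Rab26os, Crip1 and Fcgr3. Urah, a uric acid pathway gene at 0.202 and 128 FPKM, was among the 10 largest, and TrnP was listed at 0 without LPS. Chosen after their values were seen, S100a4, a calcium-binding protein gene, was 1506 and 243 FPKM, and Mgst3 was 52.7 and 7.65. The authors' deposited table calls 36 loci higher and 9 lower. The share of 2-fold genes that were higher was 59.6%, and 49.2% with upper-quartile scaling.

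The high density library is the numerator of the first ratio and the denominator of the second, so its error alone gives the 2 ratios opposite signs, and part of any excess of opposite pairs may come from it. Of 10519 genes measured in both comparisons, 115 were higher at high density and lower with LPS, against 22.4 for independent lists. In the opposite order, 32 were lower at high density and higher with LPS, against 5.15. Higher in both were 24, against 26.3, and lower in both was 1, Ttc39aos1, against 4.38. Unchanged genes simulated with the noise implied by the authors' deposited table gave means of 309, 235, 32.4 and 21.3 for these 4 counts, all above the observed ones. The same simulation gave 641 genes higher and 591 lower at high density, where 341 and 66 were observed among the 10461 genes simulated, and 984 higher and 941 lower with LPS, where 731 and 592 were observed. The implied noise was thus wider than the spread of the ratios, and the simulated counts are no fair value for unchanged genes.

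Higher in both were Nos2, Ddit3 and Isg20 (1.26 and 3.86 FPKM, then 3.50 and 45.2), with the models LOC115486847 and Gm40357, listed at 0 at low density. Ddit3 overlaps Mars and other genes, so its value may not be its own. It has q = 0.999 in both of the authors' deposited tables. Lower at high density and higher with LPS were Ccl2 and Acod1, with Gm42092, Snora16a and LOC115487878, which were listed at 0 at high density. The 5 leading genes in the opposite direction, TrnN, TrnT, Snord14c, Snord21 and LOC115489860, were listed at 0 at low density and with LPS. Tfrc, lower and then higher, and Epn2, higher and then lower, were called in both of the authors' deposited tables. Chosen after their values were seen, Ankrd37, Selenbp1 and Adm were higher at high density, at 4.39, 4.47 and 4.43, and lower with LPS, at -3.88, -2.26 and -1.48.

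**Figure D3:**
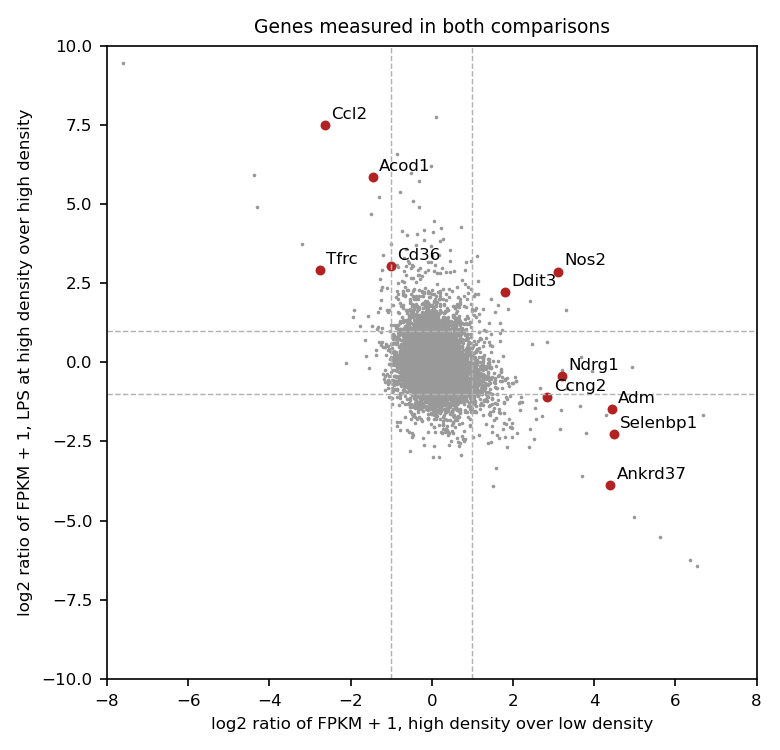
Log2 ratio of FPKM + 1 for 10519 genes, high density over low density on the horizontal axis and LPS over untreated high density on the vertical axis, with 11 genes named in red and dashed lines at 2-fold. Nos2 lies at 3.10 and 2.86 and Tfrc at -2.75 and 2.92, and 4 genes lie outside the axes.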

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

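The tests in this part on depth and on Tnf were chosen only after the result was seen. The rescaling was planned, but its use here as a test of scaling was chosen after the result was seen. Removal of the trend on length and GC was added after the data were examined. Loci without a gene symbol were set aside from the comparisons and still held differences between the libraries. At 1 FPKM or more, 113 of 685 such loci were at least 2-fold higher at high density and 18 lower, and the authors' deposited table calls 3 of them. With LPS, 138 of 767 were higher and 224 lower, and the same table calls 3.

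HIF targets were higher at high density, with a median of 1.67. After the trend on transcript length and GC was removed the median was 1.58. After rescaling without the 20 highest genes, which took the median of all genes to -0.21, it was 1.52 (95% interval of 10000 bootstrap draws over members, 1.11 to 1.94). The rescaling also evened out unequal sums: all loci summed to 665489 FPKM at low density and 766479 at high density. It therefore does not isolate the effect of the 20 highest genes. The values argue against such a trend, and against a scaling shift as large as the rescaling made, as the whole cause. Lower oxygen around crowded cells is a candidate explanation: a second list of HIF targets, written before its values were seen, had a median of 0.56 at percentile 99.99. Of its members, 5 of 20 were past 2-fold, among them Mgarp and Gys1, which overlaps Ruvbl2. With LPS, however, where the first list was lower, the median of the second list was 0.14. Oxygen was not measured, other causes of HIF activity were not tested, and with 1 library per group a difference between cultures unrelated to density stays open.

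Mitosis genes were lower with LPS. The median was -1.11 after the trend on length and GC was removed, which argues against that trend. It was also -1.11 in the 27 of 34 measured members at 20 FPKM or more without LPS. This subset holds most of the list, so its median could hardly differ from that of the list. Most members were thus not low without LPS, which argues against lost low values as the whole cause. The DNA replication median was -0.31. Cell cycle phases were not measured, so an effect of LPS on the number or phase of cycling cells stays open. So does a difference between the cultures unrelated to LPS, such as time in culture.

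Tnf was listed at 0 in every library. All 3 of Rps18, Ddx39b and Csnk2b, genes of its region that every cell uses, were also listed at 0, which argues against lack of expression as the cause for the region. Of 168 protein-coding genes with 4 rows, 3 of them on alternate scaffolds, 72.6% were listed at 0 in every library (exact 95% interval 65.2% to 79.2%), against 36.4% of 19304 genes with 1 row. Reads shared between copies may therefore have been lost there, although the 2 sets were not matched on the kind of gene.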

How the results depend on the processing

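Removal of the trend on length and GC, and leaving out short transcripts, symbols with several rows, genes listed at 0 and genes that are not protein-coding, were chosen after the data were examined. No paired analysis was possible because each group had 1 library, and no replicate could be left out. No list that stood apart and no named gene past 2-fold turned its sign under any alternative run. HIF target medians at high density ranged from 1.30 to 1.82 and mitosis medians with LPS from -1.20 to -0.89. Other medians moved further: with LPS, cytokines ranged from 1.78 to 5.09, interferon-stimulated genes from 1.61 to 3.65 and proteases from 0.54 to 1.10. Rescaling without the 20 highest genes took ATF4 targets at high density to 0.035 and lysosome genes to 0.041. Keeping status OK only removed no measured gene, and at a pseudocount of 1 no gene under 1 FPKM can pass 2-fold, so neither tests the counts. Where nothing else is said below, the cause was not tested. At a pseudocount of 0.1, genes higher and lower at high density numbered 638 and 221, and genes lower with LPS 1030. At a pseudocount of 5, which shrinks low genes by construction, they were 167 and 36 at high density, and 475 and 241 with LPS. At a log2 threshold of 1.5 they were 118 and 27, and 412 and 198. Rescaling to a fixed sum without the 20 highest genes gave 382 lower at high density and 977 lower with LPS. It also raised all values against the pseudocount and the minimum, with 11885 and 11934 genes measured against 10911 and 11010. With LPS the median gene moved only from 0.03 to -0.01, so the change in that count is not put down to a shift between the libraries. Protein-coding genes alone gave 54 lower at high density. In the authors' deposited table, calls at q under 0.01 were 0 in either direction of both comparisons, since the smallest q values are 0.0217 and 0.0174. Genes past 2-fold in both comparisons numbered 336 at a pseudocount of 0.1 and 72 at 5. By direction (higher then lower, lower then higher, higher in both, lower in both) they were 216, 59, 51 and 10 at 0.1, and 49, 14, 9 and 0 at 5. With the high density value from the other table, higher in both were 40 and lower in both 16, and with upper-quartile scaling lower in both were 3. Of the lists that stood apart at high density, LXR targets did not at a pseudocount of 5 (median 0.26), with no filter (0.24), at 5 FPKM (0.23), without the length and GC trend (0.27) and without symbols of several rows (0.27). Antigen presentation did not with no filter (0.25), at 5 FPKM (0.20), after rescaling (0.072), without the trend (0.23) and without symbols of several rows (0.33). ATF4 targets did not without the trend (0.15), nor heat shock proteins against unmatched random lists (-0.18). Of those that stood apart with LPS, LXR targets did not at a pseudocount of 0.1 (-0.38) and 5 (-0.22), with no filter (-0.25), without the trend (-0.24) and against unmatched lists (-0.38). Toll-like receptors did not at a pseudocount of 5 (0.24), at 5 FPKM (0.30) and without the trend (0.25). With no filter, which brings in unexpressed members, alternatively activated (0.16), osteoclast (0.022), YAP and TAZ (0.025), fatty acid (-0.23) and lysosome genes (0.21) did not, nor osteoclast genes after rescaling (0.26) and lysosome genes against unmatched lists (0.21). At high density, other lists came to stand apart. Macrophage identity did with no filter (-0.15), at 5 FPKM (-0.16), at a pseudocount of 5 (-0.13) and without symbols of several rows (-0.15), inflammatory cytokines at 5 FPKM (-0.34) and without the trend (-0.23), integrins without the trend (-0.16), and oxidative phosphorylation against unmatched lists (0.17). Among lists that did not stand apart, medians near 0 turned their sign. At high density, rescaling gave -0.19 for mitosis, -0.027 for osteoclast, -0.068 for oxidative phosphorylation, -0.11 for citrate cycle, -0.23 for fatty acid, -0.13 for NRF2, -0.095 for protease, -0.15 for immediate early and -0.21 for reference genes. Upper-quartile scaling gave -0.029 for mitosis, -0.071 for fatty acid, -0.0078 for immediate early and -0.050 for reference genes, and centring -0.012 for fatty acid genes. Removing the trend gave 0.0098 for YAP and TAZ, -0.067 for protease, -0.034 for fatty acid and -0.059 for immediate early genes, 5 FPKM gave -0.21 for protease and -0.0041 for fatty acid genes, and no filter 0.052 for alternatively activated genes. With LPS, macrophage identity was 0.035 with no filter, 0.094 at 5 FPKM, 0.077 without the trend and 0.094 without symbols of several rows. Heat shock proteins were -0.080 with upper-quartile scaling, -0.0056 after rescaling and -0.011 without symbols of several rows, reference genes -0.016 with upper-quartile scaling, and ribosomal proteins 0.072 without the trend. Depth limits genes near 1 FPKM, which rest on few fragments.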

Other observations

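The genes in this part were chosen after their values were seen. Genes of glycogen metabolism were higher at high density, 4 of 8 measured by 2-fold or more (median 0.94). Gbe1, the glycogen branching enzyme, was 3.95 and 30.3 FPKM, and Epm2a, the glycogen phosphatase laforin, 0.851 and 9.71. Gys1, glycogen synthase, was 22.8 and 76.8, and Gyg, glycogenin, 31.2 and 67.5. Gys1 overlaps Ruvbl2, so its value may not be its own. Gbe1 and Epm2a are called higher in the authors' deposited table (q = 0.0217). With LPS, 1 of 8 was at least 2-fold higher, Pgm1 (chromosome 5, 64092919 to 64128450), at 17.6 and 36.9 FPKM. Whether the gene of that name at this locus acts in glycogen metabolism was not checked. Epm2a was the 1 lower gene, at a log2 ratio of -1.43, while Gbe1 was at -0.82.

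Of 13 genes of iron handling measured with LPS, 5 were at least 2-fold higher and 1 lower. At high density, 0 of 12 were higher and 2 lower. The difference between the comparisons was not tested, and 2-fold ratios were also more frequent among all genes with LPS, at 947 higher and 643 lower of 11010, against 386 and 99 of 10911 at high density. With LPS, the higher genes were Lcn2, Tfrc, Hmox1, Fth1, at 7152 and 28641 FPKM, and Slc11a2, an iron importer, at 20.5 and 66.0. The lower one was Ncoa4, the ferritin autophagy receptor, at 18.1 and 8.07. The lower genes at high density were Tfrc and the metal importer gene Slc39a14, at log2 ratios of -2.75 and -1.21, and Fth1 was at 0.17, or -0.07 after rescaling without the 20 highest genes.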
